A study of Homo sapiens with 6 samples.

How the data were processed

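RNA of Daoy cells was profiled in 6 libraries, 3 with lentiviral wild-type ZBTB7B (WT) and 3 with lentiviral ZBTB7B that carries R363L in its zinc-finger domain (ZFmut). Per the labels' protocols, cells grew for 4 days in medium with 10% serum, virus was added at a multiplicity of infection of 15 for 72 hr, and libraries were made with a NEBNext Ultra RNA kit, which does not mark the strand. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

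The deposited values are raw counts of reads per gene, whole numbers without normalisation, for 60554 Ensembl gene identifiers in each file. Per the submitters' processing notes, cutadapt, TopHat2 2.0.9, HTSeq and DESeq2 were used with the GRCh38 genome; the notes give these names without their order, and the annotation release and the strand setting of the counting are not given in the sources used here. Each file ends with 5 summary lines that name no gene. They were left out of library sizes and tests, and they put 7.71 to 8.08% of the total on reads that fit more than 1 gene, 5.04 to 6.56% on reads outside genes and 16.1 to 19.4% on reads aligned to several places. Reads that align equally to paralogs or pseudogenes, and reads shared by overlapping genes, are therefore outside the gene counts. Of the named genes, DDIT4, DNAJB11, FOXM1, MCM2, NDUFA1, PAK1, PLK1, RPS2, RRM2 and TYMS each share more than 10% of their exonic sequence with other annotated genes on a single strand, and their values are less certain. This also holds for genes that overlap others on each strand. SYVN1 shares 8.4% with genes on its own strand and 6.5% with genes on the other, NDUFV1 8.4 and 4.1%, and MBP 1.9 and 8.8%. Gene symbols, positions, biotypes, exon lengths and GC content came from GENCODE release 29 on GRCh38, which held 56996 (94.1%) of the identifiers; the unmatched ones took at most 0.113% of the gene counts of any library.

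Gene counts per library ranged from 22236214 to 102730428, a 4.62-fold range, and the 10 most abundant genes took 5.57 to 5.87% of them. In chi-square tests of counts, no pair of libraries agreed within sampling noise (3.42 to 8.00 per degree of freedom within groups), so all 6 were kept as separate samples.

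Differences between WT and ZFmut were tested in R 4.3.3 with edgeR 4.0.16, using TMM normalisation, the filterByExpr filter and the two-sided quasi-likelihood F test on the deposited counts without covariates. The filter kept 18683 genes, 14658 of them protein-coding. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 differences are WT minus ZFmut with the standard error of the fit, CPM values are normalised by the TMM library sizes, and the biological coefficient of variation was 6.27%. Gene lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over 27 lists. The lists hold 544 entries for 541 distinct genes. Camera asks whether a list differs from other genes; camera with the correlation estimated per list and the rotation test fry, which asks whether the genes of a list move without comparing them with other genes, were run as alternatives. Each list's members were counted at the threshold over all tested genes and again with p-values adjusted over the list alone.

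The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names ZBTB7B, RPS6KA2, RPS6KA5 and ATXN1 in any case, and all 13 members of the list around them. It adds the 8 protein-coding genes with the largest log2 change in each direction among those with an adjusted p under 0.05, at least 1 CPM on average and no overlap between groups. From each list it takes up to 3 called members with the smallest p. Members of lists named beyond these, and the gene families in the closing section, were chosen after their values were seen. Some genes that the rule takes are not reported here. Genes on the Y chromosome and XIST were not considered for naming.

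The alternatives were other scaling factors (median of ratios, upper quartile), DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter of 5 CPM in at least 3 libraries, ZBTB7B or the mitochondrially encoded genes left out, each library left out in turn, the replicate number as a block, and a test against a minimum fold change of 1.5. Chosen after seeing the data were a correction for GC content and exon length (loess trends per library with a span of 0.5, used as offsets), the same with the block, and thinning of all libraries to the smallest total.

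The tests were run on simulated data with known answers. Counts for the 18683 genes were drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. These genes, and 30 more shifted by 0.5 for the list tests, came from genes above 1 CPM on average. The shares recovered therefore do not cover less abundant genes. The edgeR test recovered 54% of genes changed 1.25-fold, 84% at 1.5-fold and 100% at 2-fold and at 4-fold, and 7.66% of its calls were false. With GC trends per library taken from the real libraries added, 31.5% of its calls were false, and after GC and length correction 5.88%. In numbers, false calls were 16 without the trends, 82 with them and 12 after correction. These shares depend on how few genes the simulation changed and are not the share of false calls in the real data. In the simulated list tests, a shift of 0.5 in 30 genes was called by camera with both kinds of correlation, and 0 of 20 unchanged lists were called. Genes were drawn independently and without GC trends there. The simulation therefore does not cover real lists, whose genes can move together.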

Results

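Transcripts were measured by RNA sequencing in 6 libraries made from total RNA of Daoy cells, an established human line from a cerebellar medulloblastoma. Cells of 3 libraries overexpressed wild-type ZBTB7B (WT) and cells of 3 libraries overexpressed ZBTB7B with the zinc-finger substitution R363L (ZFmut), both from lentivirus at a multiplicity of infection of 15 for 72 hr. ZBTB7B, also called ThPOK, is a zinc-finger transcription factor best known from the choice of the CD4 lineage by T cells. Reads assigned to genes numbered 28429913, 56873989 and 31401429 in WT replicates 1 to 3, and 22236214, 24729078 and 102730428 in ZFmut replicates 1 to 3. The comparison asks which transcripts depend on an intact zinc-finger domain of ZBTB7B. The series belongs to work on kinases that act on ATXN1, the gene of spinocerebellar ataxia type 1, in which ZBTB7B was placed upstream of RPS6KA2, the gene of the kinase RSK3. All directions below are for WT against ZFmut, with n = 3 libraries in each group and no library without the transgene among the samples.

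RPS6KA2 transcripts were 4.01-fold higher with WT ZBTB7B, at 131 ± 5.92 CPM (read counts normalised to library size, mean ± SD) against 32.5 ± 1.83 CPM. SUCNR1, the receptor for extracellular succinate, was 49.1-fold higher, and SHC2, an adaptor of receptor tyrosine kinases, was 8.96-fold lower. Of 26 tested genes of nuclear factor kappa B (NF-kB) signalling and inflammation, 17 were higher and 3 lower. All 13 protein-coding transcripts of the mitochondrial genome were higher by a small amount, and 20 of 30 cytosolic ribosomal protein genes were lower by a small amount. Across 18683 tested genes, 3442 were higher and 3207 lower with WT by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p threshold of 0.05. Of these, 491 were at least 2-fold higher and 293 at least 2-fold lower.

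ZBTB7B (ENSG00000160685.13, GRCh38 chromosome 1, 155002630 to 155018522, plus strand) was among the abundant transcripts in every library. It reached 899, 863 and 951 CPM in WT replicates 1 to 3, and 555, 547 and 627 CPM in ZFmut replicates 1 to 3. The group means were 904 ± 44.3 and 576 ± 43.8 CPM, a log2 difference of 0.65 ± 0.06 (SE, edgeR adjusted p = 1.39e-06). WT libraries therefore held 1.57 times as much ZBTB7B transcript as ZFmut libraries. After correction for GC content and gene length the log2 difference was larger, at 0.83 (edgeR adjusted p = 1.22e-10). Counts per gene add the transgene and the cell's own ZBTB7B, so the part of this difference that lies in the transgene is not known, and the reads that carry the substitution were not analysed here.

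RPS6KA2 (ENSG00000071242.11, chromosome 6, 166409364 to 166906451, minus strand) was higher by 2.0 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 1.96e-11), and its lowest WT library, at 125 CPM, lay above its highest ZFmut library, at 34.5 CPM. ATXN1 (ENSG00000124788.17, chromosome 6, 16299112 to 16761491, minus strand) was higher by 0.25 ± 0.05, at 141 ± 3.80 against 119 ± 3.74 CPM (edgeR adjusted p = 0.00170), and by 0.14 after correction for GC content and gene length (edgeR adjusted p = 0.00961). RPS6KA5 (ENSG00000100784.9, chromosome 14, 90847862 to 91060636, minus strand), the gene of the kinase MSK1, missed the threshold with a log2 difference of 0.27 ± 0.10 at 11.7 ± 0.607 against 9.68 ± 1.51 CPM (edgeR adjusted p = 0.0504). Without ZFmut replicate 1, the RPS6KA5 difference was 0.34 and passed (edgeR adjusted p = 0.00898); after that correction it was 0.12 and did not (0.241). Over the alternatives other than the minimum fold change of 1.5, its adjusted p ranged from 0.00386 to 0.241.

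The list that held these genes with the remaining RSK and MSK kinases and the partners and regulators of ATXN1 had 13 members, of which 4 were higher, 2 lower and 7 did not pass (7 higher and 2 lower when adjusted over the list alone). PAK1, a p21-activated kinase, was higher by 0.44 ± 0.06 (edgeR adjusted p = 3.93e-05). RPS6KA4, the gene of MSK2, was lower at a log2 difference of -0.37 ± 0.09 (edgeR adjusted p = 0.00524). CIC, a repressor that binds ATXN1, was lower at -0.27 ± 0.08, a call that ended without WT replicate 1 (-0.20, edgeR adjusted p = 0.0598) and without ZFmut replicate 3 (-0.20, edgeR adjusted p = 0.105). The log2 differences of RPS6KA3, ATXN1L, RBM17, RPS6KA1 and RPS6KA6 were 0.15, 0.13, 0.05, -0.03 and -0.12 and did not pass. Without ZFmut replicate 1, 7 members were higher, with RPS6KA3 at 0.22 (edgeR adjusted p = 0.00243), ATXN1L at 0.15 (0.0430) and RPS6KA5 among them. With the replicate block, RPS6KA3 passed at 0.16 (edgeR adjusted p = 0.00125), and ATXN1L at 0.13 (0.0147) and RPS6KA5 did too. After GC and length correction, RPS6KA4 was at -0.20 (edgeR adjusted p = 0.000875), CIC at -0.15 (0.00374) and RPS6KA3 at 0.014 (0.797). RPS6KA6 was then lower at -0.27 (edgeR adjusted p = 0.00797) and ATXN1L higher at 0.14 (0.0140). As a set the list did not pass camera (adjusted p = 0.131; adjusted p = 0.509 with an estimated correlation), except with DESeq2.

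**Figure D1:**
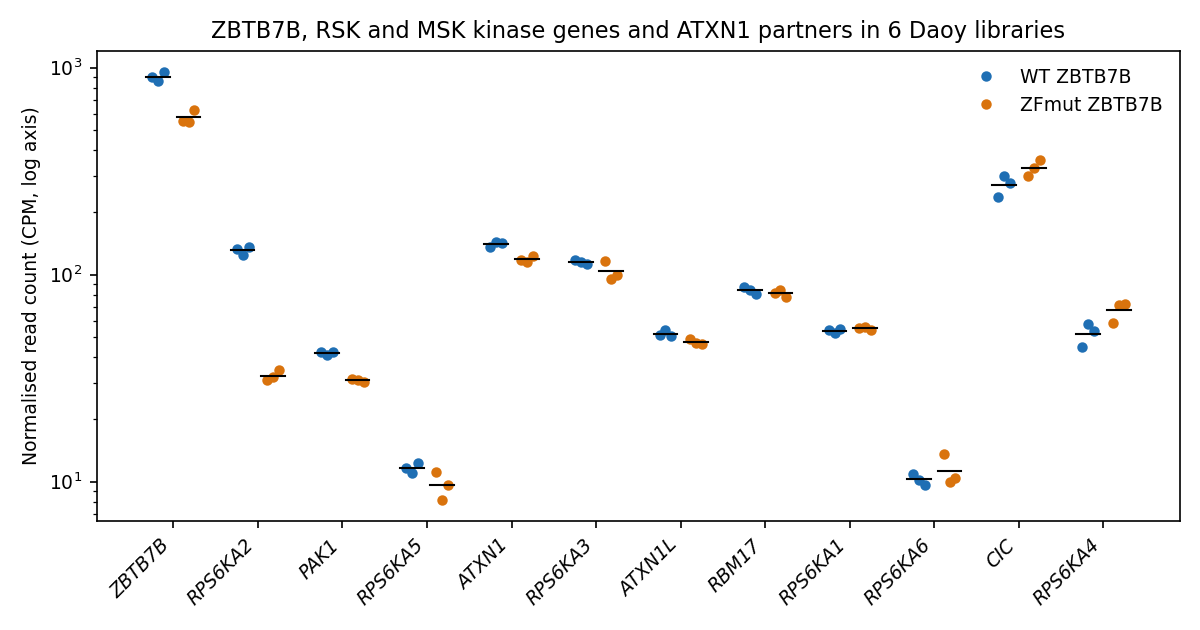
Normalised read counts (CPM, log axis) of 12 of the 13 genes of the ZBTB7B, kinase and ATXN1 list; each point is a library, blue for WT and orange for ZFmut, and bars are means of 3 libraries. RPS6KA2 shows the widest gap, 131 against 32.5 CPM on average.

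Apart from SUCNR1, at 45.4 ± 6.42 against 0.875 ± 0.217 CPM (log2 difference 5.62 ± 0.15, edgeR adjusted p = 6.17e-12), the protein-coding genes with the largest increases included CD36, CGA, LIPH, ASB5, INA and ABCC2. CD36, a receptor for fatty acids and oxidised lipoproteins, was 22.3-fold higher. CGA, the shared alpha subunit of the glycoprotein hormones, was 19.5-fold higher, LIPH, a lipase that makes lysophosphatidic acid, 18.6-fold, and ASB5 15.5-fold. INA, a neuronal intermediate filament, rose from 0.531 ± 0.175 CPM with ZFmut to 7.67 ± 0.250 CPM with WT, and the export pump gene ABCC2 from 1.36 ± 0.139 to 15.95 ± 3.17 CPM. Reads were few with ZFmut: CD36 had 0, 3 and 17 reads in ZFmut replicates 1 to 3. Each of these 7 genes, SUCNR1 included, passed in every fit that left out a library, with the CD36 difference at 5.46 without ZFmut replicate 3 in place of 4.48.

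The largest decreases with WT began with SHC2, at 3.11 ± 0.302 against 28.0 ± 2.85 CPM (log2 difference -3.16 ± 0.10, edgeR adjusted p = 5.07e-11). DMBT1, a secreted scavenger receptor of epithelia, was 7.80-fold lower, and PDK4, a kinase that restrains the pyruvate dehydrogenase complex, 6.19-fold lower. MISP, a protein of the cell cortex that positions the mitotic spindle, was 5.58-fold lower, and SOHLH1, a transcription factor of germ cells, 5.40-fold lower. TMEM176A was 5.24-fold lower, UNC13D, which acts in granule release, 5.11-fold lower, and the matricellular protein gene WISP2 5.08-fold lower.

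**Figure D2:**
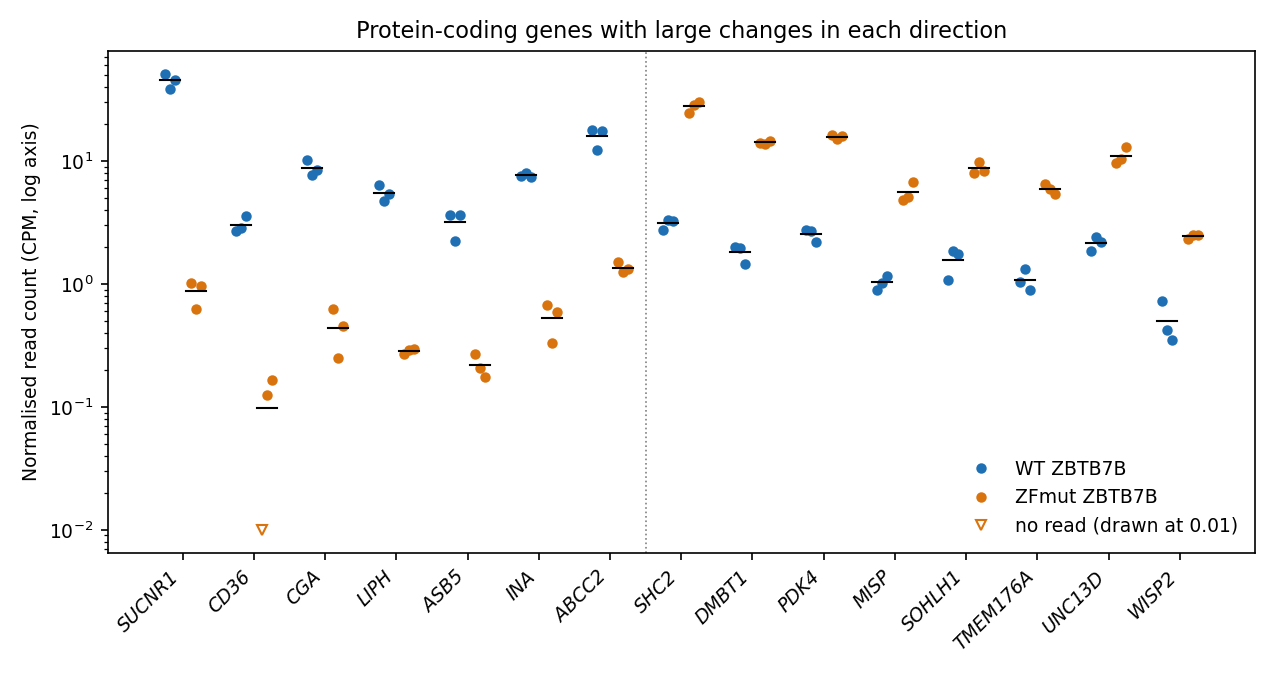
Normalised read counts (CPM, log axis) of 7 protein-coding genes among those with the largest increase and the 8 with the largest decrease; points are libraries (WT blue, ZFmut orange), bars are means of 3 libraries, and an open triangle marks a library without reads. SUCNR1 averaged 45.4 CPM with WT and 0.875 CPM with ZFmut.

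Among inflammatory genes, TNFAIP3, which restrains NF-kB signalling, was 2.47-fold higher, and the monocyte chemoattractant CCL2 was 2.75-fold higher, at 17.8 ± 2.88 against 6.20 ± 0.811 CPM. The cytokine gene IL32 went the other way, 1.88-fold lower, and IL11 and LIF were lower too. The counts of 17 higher and 3 lower of 26 became 19 and 3 when adjusted over the list alone, and the list's median log2 difference was 0.69. The list passed camera (adjusted p = 0.000148), but not with the correlation among its genes estimated from the libraries, which was 0.041 (adjusted p = 0.509 with the estimated correlation). With such estimates camera called 0 of the 27 lists. Adjusted p rose even where the estimate was under 0, as for the glial markers at -0.010 (camera adjusted p from 0.131 to 0.509). Loss of a call with an estimated correlation therefore does not show that the genes of a list move together. With only genes of at least 5 CPM in 3 libraries tested, 7 members were higher and 3 lower, the median was 0.18, and camera no longer called the list (adjusted p = 0.312). CXCL5 rested on 61 reads with WT and 2 with ZFmut, a ratio of 39.1 with a 95% exact binomial interval of 10.4 to 330.

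Interferon-induced genes moved in both directions, with 17 higher and 9 lower of 39 tested (20 and 10 adjusted over the list alone, 19 and 6 after GC and length correction; median 0.20). SAMD9L, an antiviral effector, was 2.88-fold higher at 57.1 ± 3.59 CPM, DDX60 1.80-fold and IFIT3 1.74-fold higher, whereas BST2 and IFITM3 were among the lower members. The list did not pass camera (adjusted p = 0.120; adjusted p = 0.509 with an estimated correlation), though it did with DESeq2, limma-voom and no low-count filter, and without ZFmut replicate 3, 4 members were lower. Of 15 genes of antigen presentation, 3 were higher and 1 lower, the same over all genes and adjusted over the list alone, and 6 and 0 after GC and length correction (camera adjusted p = 0.812). ERAP1, an aminopeptidase that trims peptides for display, was 1.41-fold higher. TAPBP was lower at -0.25 ± 0.07, not past the threshold after GC and length correction (-0.09, edgeR adjusted p = 0.0542) or without ZFmut replicate 3 (-0.20, 0.0607). Without WT replicate 2, 1 member was higher.

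The 13 mitochondrially encoded genes rose together, by a median of 0.25 on the log2 scale (13 higher adjusted over the list alone; camera adjusted p = 5.75e-05; adjusted p = 0.509 with an estimated correlation). MT-ND3 was higher by 0.41 ± 0.05, MT-ND6 by 0.34 ± 0.05 and MT-CYB by 0.31 ± 0.04. After GC and length correction 11 of the 13 were higher. The share of all gene counts on the mitochondrial genome, with its ribosomal and transfer RNA genes, was 4.02, 4.00 and 3.95% in the WT libraries and 3.40, 3.39 and 3.25% in the ZFmut libraries. The 23 nuclear genes of oxidative phosphorylation showed no such shift, with 4 higher and 3 lower (4 and 2 adjusted over the list alone, 2 and 4 after GC and length correction). Their median was -0.01 and their mean 0.01, camera pointed up, and its adjusted p was 0.898. COX6C and NDUFA1 were higher by 0.29 ± 0.06 and 0.27 ± 0.06, and NDUFV1 was lower at -0.29 ± 0.07 (-0.14 after GC and length correction); 44.5% of the exonic sequence of NDUFA1 overlaps a gene on the other strand. The higher count was 2 without WT replicate 1, WT replicate 2 or ZFmut replicate 3; the lower count was 1 without WT replicate 2, WT replicate 3 or ZFmut replicate 2, and 5 without ZFmut replicate 1.

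Ribosomal protein genes went down by a median of -0.20, with 20 of 30 lower and 0 higher (26 lower adjusted over the list alone). RPS2 was lower at -0.36 ± 0.07 and RPL10A at -0.27 ± 0.05, or -0.20 and -0.17 after GC and length correction. Camera called the list (adjusted p = 4.63e-05), but not with its correlation estimated from the libraries, which was 0.824 (adjusted p = 0.889 with the estimated correlation). After GC and length correction 23 members were lower. Without WT replicate 3, 12 members were lower, and without ZFmut replicate 2, 16 were lower with a median of -0.13. ZFmut replicate 2 stood apart from its group. Relative to the average of all libraries, the list mean was 0.226 there and 0.020 and 0.046 in ZFmut replicates 1 and 3. In the WT libraries it ran from -0.114 to -0.069. Many ribosomal protein genes have processed pseudogenes, which compete for the same reads, so single members are uncertain. Of 14 tested replication-dependent histone genes 4 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.419), among them HIST1H1C by 0.35 ± 0.05 and HIST1H4H by 0.47 ± 0.12. HIST1H2BC, higher by 0.50 ± 0.18, lost its call in DESeq2 (adjusted p = 0.136), with no low-count filter (edgeR adjusted p = 0.0669) and when WT replicate 2 or 3 or ZFmut replicate 1 or 2 was left out (edgeR adjusted p from 0.0662 to 0.126). Without WT replicate 2 or WT replicate 3, 2 histone genes were higher. Of 14 heat shock genes 1 was lower and 0 were higher, also adjusted over the list alone (camera adjusted p = 0.792); after GC and length correction 4 were lower and 2 higher. The gene called in the main fit, HSP90AB1, at -0.16 ± 0.04, missed the threshold without WT replicate 3 (-0.15, edgeR adjusted p = 0.0617).

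Targets and feedback inhibitors of ERK signalling included 9 higher and 4 lower genes of 20 (10 and 4 adjusted over the list alone, 11 and 2 after GC and length correction; median 0.18; camera adjusted p = 0.271, with a call in DESeq2, and 0.889 with an estimated correlation). DUSP4, a phosphatase that inactivates ERK, was 1.98-fold higher, the immediate-early gene EGR1 1.65-fold and SPRY4, an inhibitor of receptor tyrosine kinase signalling, 1.57-fold, while MYC and ETV4 were among the lower members. Without ZFmut replicate 3, 2 members were lower. Of 18 targets of TGF-beta and YAP signalling, 9 were higher and 2 lower, also adjusted over the list alone (median 0.20). ID2 was 1.80-fold and CYR61 1.45-fold higher. The list did not pass camera (adjusted p = 0.0720), so its call depends on the fit. It passed with DESeq2, limma-voom, no low-count filter and the replicate block, and without WT replicate 1. It also passed after GC and length correction, with 12 higher and 2 lower (camera adjusted p = 0.00504; adjusted p = 0.863 with an estimated correlation). Collagen and matrix genes split, with 10 higher and 14 lower of 32, also adjusted over the list alone (median -0.01, camera adjusted p = 0.792). COL5A2 was 1.87-fold and the proteoglycan gene VCAN 1.44-fold higher, whereas COL7A1, the collagen of anchoring fibrils, was 2.72-fold lower, at 132 ± 12.7 against 359 ± 19.0 CPM, and COL1A1 was lower as well.

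Hedgehog pathway genes, relevant to a medulloblastoma line, had 2 higher and 4 lower members of 13, also adjusted over the list alone (median -0.11, camera adjusted p = 0.507), and 4 and 6 after GC and length correction. The higher ones were GLI1 at 0.34 (edgeR adjusted p = 0.00734) and PTCH1 at 0.14 (0.0472), both transcribed in response to the pathway. FOXM1 was lower at -0.36 ± 0.06 and SFRP1 at -0.21 ± 0.05. HHIP, at -0.73 ± 0.17, missed the threshold without ZFmut replicate 3 (-0.62, edgeR adjusted p = 0.0548). Of the 7 genes of 14-3-3 proteins, which bind phosphorylated ATXN1, 2 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.566). YWHAZ was higher by 0.23 ± 0.05, and by 0.12 after GC and length correction. YWHAG, higher by 0.16 ± 0.05, lost its call with no low-count filter (edgeR adjusted p = 0.0571) and without WT replicate 1 or 3 or ZFmut replicate 2 or 3 (0.0510 to 0.133). SFN, at -0.34 ± 0.10, lost its call after GC and length correction (-0.16, edgeR adjusted p = 0.123), after thinning (-0.24, 0.106) and without WT replicate 3 or ZFmut replicate 2 or 3 (0.0509 to 0.120). Among the 5 tested relatives of ZBTB7B, itself included, ZBTB7B was higher and ZBTB7A lower at -0.24 ± 0.09 (1 and 1 also adjusted over the list alone). The call of ZBTB7A ended after GC and length correction (-0.09, edgeR adjusted p = 0.138), with the stricter filter (0.0598) and without WT replicate 1 or ZFmut replicate 2 or 3 (0.0635 to 0.284). That list had a median of -0.06 and a mean of 0.01, and camera pointed down (adjusted p = 0.792).

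In the cell cycle, 14 of 27 S phase genes were lower and 2 higher (15 and 3 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0582). Camera called the S phase list with upper-quartile factors, DESeq2, limma-voom, no low-count filter and the replicate block, and without ZFmut replicate 1 or 3, but not with an estimated correlation (adjusted p = 0.882). The thymidylate synthase gene TYMS was lower at -0.38 ± 0.07 and the replicative helicase gene MCM2 at -0.29 ± 0.07 (-0.16 after GC and length correction), while RRM2, a subunit of ribonucleotide reductase, was higher by 0.29 ± 0.05. TYMS, MCM2 and RRM2 share 46.6, 23.6 and 20.2% of their exonic sequence with other annotated genes. The lower count was 8 without WT replicate 1, 7 without WT replicate 3, 8 without ZFmut replicate 2 and 8 without ZFmut replicate 3. Of 31 genes of G2 and M phase, 5 were lower and 0 higher, also adjusted over the list alone (median -0.02, camera adjusted p = 0.358), and the lower count was 3 without WT replicate 3. They included PLK1 at -0.36 ± 0.06, CDC20 at -0.33 ± 0.06 and AURKB at -0.25 ± 0.06, which drive mitosis; the last 2 were at -0.21 and -0.14 after GC and length correction. After GC and length correction, 15 genes of G2 and M phase were lower and camera called both lists (adjusted p = 0.0253 for S phase and 0.00246 for G2 and M phase; adjusted p = 0.866 for each with an estimated correlation).

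Targets of p53 went both ways, with 5 higher and 7 lower of 20 (8 and 7 adjusted over the list alone, 6 and 4 after GC and length correction; median 0.08, camera adjusted p = 0.792). CDKN1A, which encodes the cell cycle inhibitor p21, was 1.84-fold higher, at 80.2 ± 2.03 against 43.6 ± 0.594 CPM, and TP53INP1 1.80-fold higher, while the stress cytokine gene GDF15 was 1.93-fold lower. The lower count was 3 without WT replicate 1, ZFmut replicate 2 or ZFmut replicate 3, and 4 without WT replicate 3. Of 25 targets of ATF4, the transcription factor of the integrated stress response, 4 were higher and 10 lower (4 and 11 adjusted over the list alone; median -0.08, camera adjusted p = 0.411). ATF3 was 2.0-fold higher; DDIT4, an inhibitor of mTORC1, was 1.72-fold lower, and PHGDH, the entry enzyme of serine synthesis, 1.45-fold lower. DDIT4 shares 41.2% of its exonic sequence with a gene on the other strand. Genes of protein folding in the endoplasmic reticulum had 4 higher and 2 lower members of 20, also adjusted over the list alone (median 0.01, camera adjusted p = 0.792), with DNAJB9 higher by 0.42 ± 0.09 and DNAJB11 by 0.30 ± 0.05 (0.19 after GC and length correction). SYVN1, at -0.25 ± 0.06 (-0.13 after that correction), missed the threshold without ZFmut replicate 3 (-0.21, edgeR adjusted p = 0.0602). The higher count was 2 without WT replicate 1 or 3 or ZFmut replicate 2 or 3.

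Of 23 sterol synthesis genes 4 were higher and 5 lower, also adjusted over the list alone, and 5 and 7 after GC and length correction (median -0.03, camera adjusted p = 0.587). SC5D was higher by 0.56 ± 0.07, and LSS, the gene of lanosterol synthase, was lower at -0.32 ± 0.06 (-0.21 after GC and length correction). The lower count was 3 without WT replicate 1 or 3 and 2 without ZFmut replicate 3. Of 17 fatty acid synthesis genes 2 were higher and 6 lower, also adjusted over the list alone (median -0.05, camera adjusted p = 0.507), among the lower ones the desaturase FADS1 at -0.42 ± 0.05, GPAM at -0.33 ± 0.06 and ATP citrate lyase, ACLY, at -0.32 ± 0.05; without WT replicate 1, 3 were lower. Hypoxia and glycolysis genes split into 9 higher and 7 lower of 22, also adjusted over the list alone (median 0.06, camera adjusted p = 0.812). The glycolytic activator gene PFKFB3 was 1.67-fold and NDRG1 1.48-fold higher, and the neuronal enolase gene ENO2 1.49-fold lower. After GC and length correction the median of this list was -0.01 and camera pointed down. Of the 8 tested genes of brown fat and milk, tissues in which ZBTB7B has known roles, 4 were higher and 2 lower (4 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 0.675). DIO2, which activates thyroid hormone, was 2.10-fold and PPARGC1A 1.40-fold higher, and PPARG was 1.34-fold lower.

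None of the 3 lists of markers of other cell types passed camera in the main fit. The glial list passed with DESeq2, without WT replicate 1 and after GC and length correction with the replicate block, and the neuronal list with DESeq2; neither passed with an estimated correlation (adjusted p = 0.509 and 0.889). Of 14 tested neuronal markers 4 were higher and 3 lower (4 and 4 adjusted over the list alone; median 0.07, camera adjusted p = 0.587). Beside INA, the microtubule protein gene MAP2 was 2.46-fold higher, and the neural adhesion molecule NCAM1 was 2.25-fold higher, at 193 ± 3.04 against 85.8 ± 1.96 CPM. SNAP25 and ELAVL4 were among the lower members, and STMN2 and DCX were too low to test, at no more than 0.264 and 0 CPM. Of 9 tested glial markers 5 were higher and 2 lower, also adjusted over the list alone (median 0.55, camera adjusted p = 0.131; adjusted p = 0.509 with an estimated correlation), and 3 were higher without WT replicate 2 or ZFmut replicate 3. The water channel gene AQP4 was 16.6-fold higher at 1.51 ± 0.309 CPM, MBP, a myelin protein, 1.92-fold, and SLC1A3, a glutamate transporter, 1.56-fold, while GFAP and OLIG2 were lower. Of 10 tested lymphoid markers, taken because ZBTB7B acts in T cells, 2 were higher and 2 lower, also adjusted over the list alone (median -0.04, mean 0.01, camera pointing down with adjusted p = 0.933). GATA3 was 2.52-fold higher and RUNX3 1.30-fold lower (log2 difference -0.38, and -0.23 after GC and length correction). CD4, at 0.739 ± 0.284 against 1.32 ± 0.170 CPM (log2 difference -0.77 ± 0.25), lost its call in DESeq2 (adjusted p = 0.0691), after thinning (edgeR adjusted p = 0.0795) and without WT replicate 1 or 3 or ZFmut replicate 3 (0.0608 to 0.147); with a library left out the difference ran from -0.58 to -1.21. CD3D, CD8A and PTPRC stayed under 0.5 CPM in every library, at highest values of 0.405, 0.315 and 0.246 CPM.

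**Figure D3:**
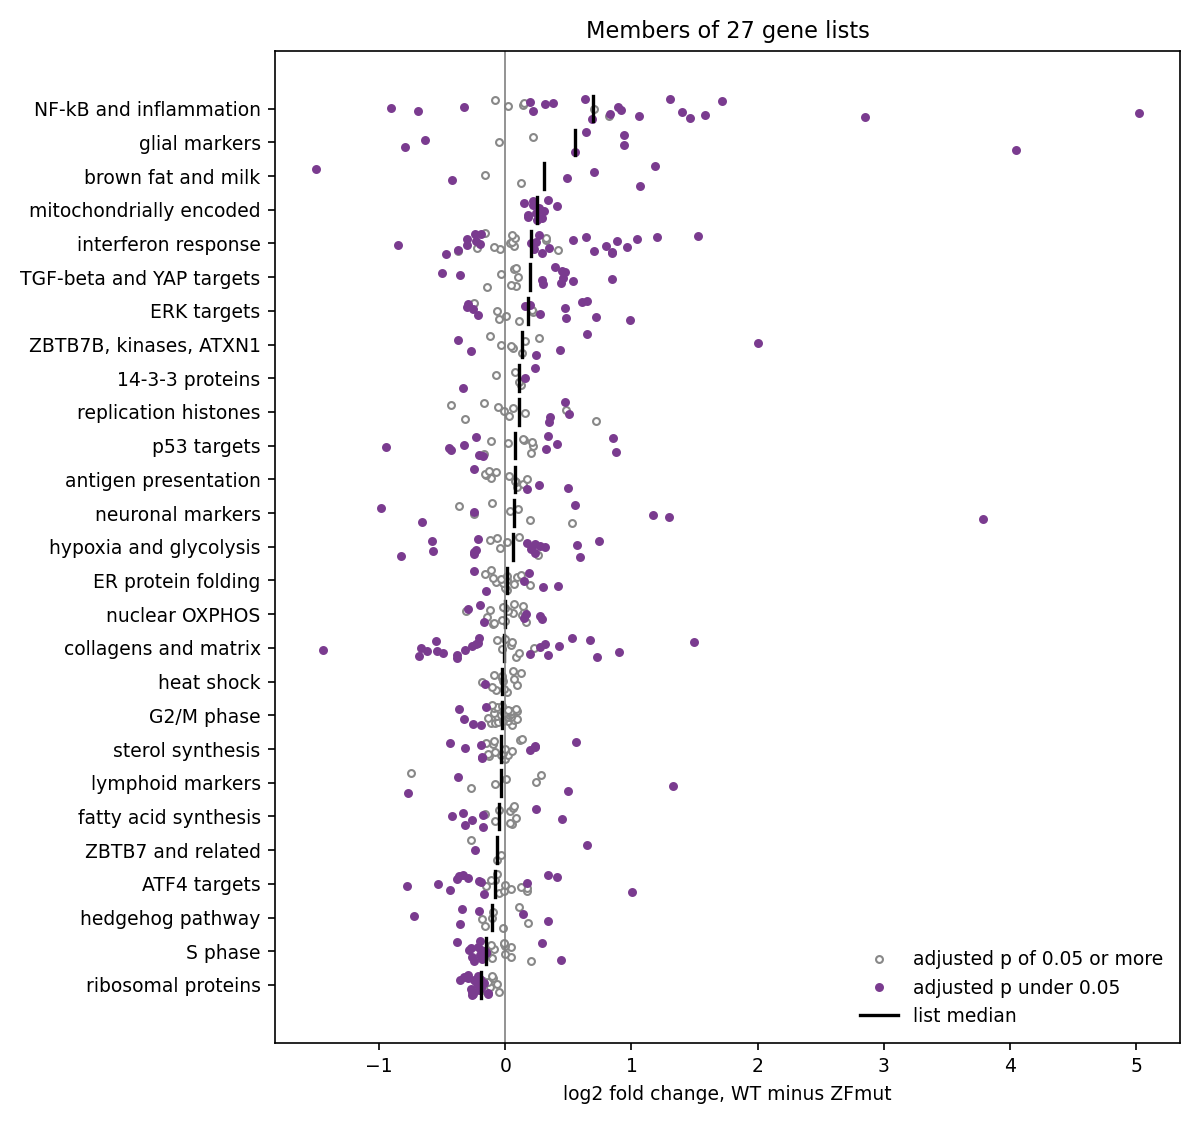
The log2 fold change (WT minus ZFmut) of each tested member of the 27 gene lists, sorted by list median; filled points passed the edgeR adjusted p threshold of 0.05, open points did not, and black bars are medians. NF-kB and inflammation genes have the highest median, 0.69, and ribosomal protein genes the lowest, -0.20; the rightmost point is CXCL5, which rested on 2 reads with ZFmut.

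Of the 6649 calls, 2362, or 35.5%, lay under 0.3 on the log2 scale, a 1.23-fold change, and the median size of a called difference was 0.383. In 8811 genes, 47.2% of those tested, the groups did not overlap, where chance gives 10%. Across protein-coding genes, the log2 difference fell with GC content (Spearman rho = -0.346 across genes, which are not independent replicates), and from the lowest to the highest decile of GC content the share of higher genes went from 32.3 to 12.8% and that of lower genes from 3.41 to 35.7%. The trend differed between libraries: rho of GC content with the deviation of log2 CPM from the gene mean was -0.480, -0.104 and -0.208 in WT replicates 1 to 3, and -0.146, 0.447 and 0.453 in ZFmut replicates 1 to 3. After correction for GC content and length, 5619 of the 6649 calls (84.5%) kept their sign and passed, among them 782 of the 784 calls of at least 2-fold but 1546 of the 2362 calls under 0.3. The corrected test called 3933 genes higher and 3761 lower.

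**Figure D4:**
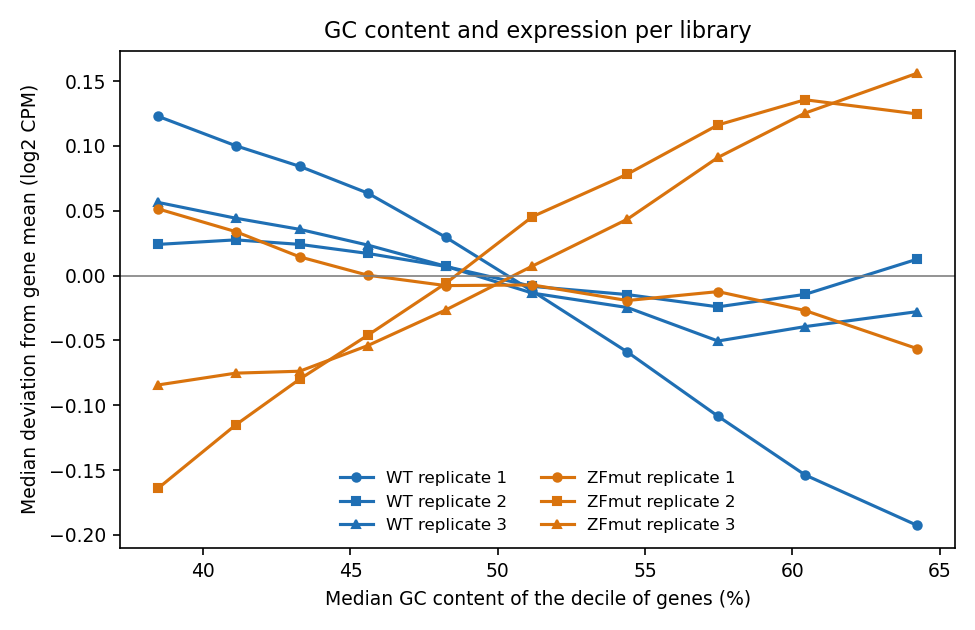
Median deviation of expression from the gene mean (log2 CPM) by decile of GC content (%), as lines for the 6 libraries (WT blue, ZFmut orange; circle, square and triangle for replicates 1, 2 and 3). ZFmut replicates 2 and 3 rise with GC content, with rho of 0.447 and 0.453, whereas ZFmut replicate 1 lies within the range of the WT libraries at -0.146.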

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

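The GC and length correction, its fit with the replicate block, and thinning to equal totals were chosen after the results were seen; the other alternatives were planned. Of 102 named genes, 85 kept direction and side of the threshold in every alternative run on them. The test against a minimum fold change of 1.5 was left out of this count and of the gene values and list member counts that follow. Over 1820 gene values 37 lost and 13 gained a call; of 972 list member counts, 112 were lower and 39 higher by more than 1.5 times. Calls were 3442 higher and 3207 lower, and 433 and 272 against a minimum fold change of 1.5. With a library left out they ran from 2504 to 3782 higher and from 2266 to 3934 lower. RPS6KA5, at 0.27, passed with limma-voom (0.27), without the low-count filter (0.26), with the replicate block (0.29), after thinning (0.32) and without ZFmut replicate 1; with a library left out it ran from 0.18 to 0.34. Differences that did not pass changed sign after GC and length correction, without and with the block: RBM17 to -0.048 and -0.054, RPS6KA1 to 0.081 and 0.080. Camera called 3 lists, and with DESeq2 statistics 10, limma-voom 6, no filter 6, the replicate block 5, GC and length correction 6, the same with the block 7, a library left out 3 to 5, and an estimated correlation 0. Of 27 lists, fry called 12 by direction and 27 when directions could mix. The cause of these changes was not tested. The replicate numbers were not taken to pair samples, since same-numbered deviations from group means correlated at 0.165, 0.0770 and 0.0635, not all above 0.1, although each sample correlated best with its own number, a hint from the data. The replicate block gave 4466 higher and 4226 lower genes. Thinned to equal totals, 17740 genes were tested, 3049 higher and 2857 lower.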

Other observations

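The tests of gene families, of the GC trend, of the RPS6KA2 response and of the corrected list means, and the counts over other splits, were written down after the results they concern had been seen; the tests of list shifts between single libraries were written before. Among 394 families of protein-coding genes that share the start of their symbol and have at least 6 tested members, 4 held more called genes in a direction than other genes did (one-sided Fisher's exact tests, Benjamini-Hochberg over 788 tests; genes of a family are not independent). All 7 tested CXCL chemokine genes were higher with WT (adjusted p = 0.00720; 0.0184 after GC and length correction), including CXCL16 at 59.9 ± 3.80 against 40.0 ± 3.28 CPM and CXCL14 at 4.40 ± 0.0560 against 3.20 ± 0.230 CPM, which lie outside the NF-kB list. The others, CXCL1, CXCL2, CXCL3, CXCL5 and CXCL8, are members of that list with few reads, at 0.530 to 2.10 CPM with WT. The family result therefore partly repeats that list. Of 49 tested RPL genes 24 were lower (adjusted p = 0.00310; 36 lower and 1.29e-10 after correction). Of 15 protocadherin beta genes, adhesion molecules encoded in a neural gene cluster, 10 were higher and 0 lower (adjusted p = 0.0416), with PCDHB2 at 20.1 ± 1.17 against 12.0 ± 0.428 CPM. Of 11 keratin genes 8 were lower and 0 higher (adjusted p = 0.0416), with KRT8 at 263 ± 19.0 against 461 ± 50.5 CPM and its partner KRT18 at 110 ± 1.37 against 130 ± 14.6 CPM. After GC and length correction 10 protocadherin beta genes were still higher, with a median log2 difference of 0.436 (quartiles 0.335 and 0.555) against 0.450 (0.287 and 0.556) before. The family's adjusted p rose to 0.0645 with the same members called, as calls among all tested genes rose from 3442 to 3933 higher. For keratin genes the median went from -0.460 (quartiles -0.769 and -0.345) to -0.317 (-0.595 and -0.262), 7 were lower, and the adjusted p rose to 0.237. Whether either family stands out from other genes is open. Correction called 5 families lower in place of 2: RPL, RPS, MCM, CCT and EIF, the last 4 at an adjusted p of 0.0343 each. Protocadherin beta genes are similar in sequence and lose reads that align to several members.

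Of 6 tested genes of the HES family, some of them targets of Notch signalling, 5 were higher. HES4 was higher by 1.59 ± 0.07, HES7 by 1.05 ± 0.10 and HES1 by 0.61 ± 0.05 on the log2 scale. HES2 and HES5 were higher as well, at under 1 CPM. The family did not pass over all families (adjusted p = 0.179). Among PNMA genes 5 of 7 were lower, PNMA3 at 3.43 ± 0.186 against 8.68 ± 0.658 CPM (family adjusted p = 0.313). MMP genes had 9 higher and 3 lower members of 15 (family adjusted p = 0.130).

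RPS6KA2 was 4.01-fold higher with WT. A response in proportion to the 1.57-fold difference in ZBTB7B transcript, transgene and the cell's own together, is argued against. The log2 change of RPS6KA2 exceeded that of ZBTB7B by 1.35 ± 0.08 (SE). After GC and length correction the changes of RPS6KA2 and ZBTB7B were 2.07 and 0.83. How much of the ZBTB7B difference lies in the transgene is not known. A response in proportion to the transgene alone therefore stays open. The GC and length trend is argued against as well, since the change was 2.07 after correction. The data are consistent with RPS6KA2 depending on the zinc-finger domain, as a hypothesis. A steeper than proportional response to the amount of ZBTB7B, and an effect of the mutant itself, stay open, because no library lacked the transgene.

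GC-rich genes were lower and GC-poor genes higher with WT. GC bias of single libraries may be the source: rho of the deviations from gene means ranged by 0.599 within ZFmut, above the size of the difference between group means of -0.515, and ZFmut replicate 1 lay among the WT libraries. An exact two-sided permutation test of rho between the groups gave p = 0.200 where the smallest possible is 0.100, and an effect of the genotype on GC-rich genes stays open, untested. The trend is small beside calls of at least 2-fold, with decile medians of the log2 difference from 0.127 to -0.154. Correction could therefore hardly remove such calls, and 99.7% stayed. The size of the trend argues against it as their cause. For calls under 0.3, 65.5% stayed, which leaves open how many of them follow the trend.

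Mitochondrially encoded genes were higher and ribosomal protein genes lower with WT. For the mitochondrial list, a GC and length trend as the whole cause is argued against by a difference of 0.19 in the list mean after correction, with no overlap of the groups and above the range within each. A shift between single libraries is argued against by a range within groups of at most 0.057, against a difference of 0.26. After correction the range within ZFmut was 0.183 against a difference of 0.191, so the corrected values are less firm against both explanations. For the ribosomal list, such a shift may contribute. Its mean ranged by 0.21 within ZFmut, where replicate 2 was highest, against a difference of -0.19 between groups. After correction 23 of its 30 members were lower, against 20 before, and camera still called it (adjusted p = 0.00101). Its genes move together, and with an estimated correlation camera did not call it (adjusted p = 0.866). There the GC and length trend as the whole cause cannot be told apart from a difference between the groups, since the corrected difference of -0.15 was smaller than the corrected range of 0.18 within ZFmut; effects of the genotype on both lists stay open, untested.

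With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 6649 genes and the highest of the others 0, so 1 split reached the real count. Every other split put WT and ZFmut libraries together in each group, where the difference between them widens the spread. The 0 calls there therefore do not show how many calls would arise by chance. For gene lists, 4 of the 10 splits, the real one included, gave at least 3 called lists, and the highest of the others gave 5.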
